A study of Homo sapiens with 12 samples.

How the data were processed

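Gene expression was measured by bulk RNA-seq in HK-2, an established line of human proximal tubule epithelial cells. The 12 libraries fell into 3 groups of 4 by their titles, genotype and treatment labels: cells with the control short hairpin RNA and no treatment (shNC), cells with the control hairpin and hydrogen peroxide (shNC_H2O2), and cells with the hairpin against YAP1 and hydrogen peroxide (shYAP1_H2O2). Hydrogen peroxide, an oxidant, was given at 150 µM for 48 h per the labels. Cells with the YAP1 hairpin and no H2O2 were not analysed here, so the effect of the hairpin without the oxidant, and an interaction of the hairpin with the oxidant, were not tested. The labels name the HK-2 line, whereas the extraction protocol speaks of kidney tissue. The values were treated as those of the cell line. The labels do not state that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

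Per the labels, libraries were made from total RNA with oligo(dT) selection and a paired-end kit for mRNA, and sequenced on an Illumina or an MGI instrument, with no label tying a library to either. Oligo(dT) selection favours polyadenylated RNA, which leaves most replication-dependent histone transcripts and noncoding RNA without a tail under-represented. The authors deposited one table of raw counts per library, with whole numbers per gene that were neither scaled nor pooled over replicates. HISAT2, featureCounts, Subread and DESeq2 are named, with the GRCh38 (hg38) genome, per the submitters' processing notes. Their versions and roles, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Because strand use is not stated, reads of a gene and of a gene overlapping it, on either strand, could not be told apart, and genes with over 20% of their exon bases in another gene are given as uncertain. So are paralogs with near-identical transcripts, such as HSPA1A and HSPA1B, the metallothioneins and the ribosomal proteins.

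Each table held 40649 genes by Ensembl identifier, of which 2049 had no count in any library and 0 named no gene. Symbols were found for 40555 identifiers in the table of gene names and for 85 more in the GENCODE annotation of GRCh38, which gave positions for 39306. Total counts ranged from 30789997 to 46582873 per library, and 3 counts, taken as the floor of detection, corresponded to 0.0644 to 0.0974 CPM, the usual scaling of counts to library size. Floors cover counting error only, since the libraries carry no molecular identifiers, whereas the 95% intervals given for YAP1 come from the standard error of edgeR and cover the spread between libraries. Between 26074 and 28257 genes had at least 1 count in a library. Counts of replicates were compared by a chi-square statistic per degree of freedom, which lay at 2.96 or above in every pair of a group, far above sampling noise, so each library was counted as 1 replicate.

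Differential expression was tested with edgeR 4.0.16 under R 4.3.3 on the deposited counts. Genes were filtered with filterByExpr by group, which left 19268. Libraries were scaled with TMM factors, dispersions were estimated (common dispersion 0.0163), and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, with 9 residual degrees of freedom before pooling across genes. The 3 contrasts were shNC_H2O2 minus shNC, shYAP1_H2O2 minus shNC_H2O2, and shYAP1_H2O2 minus shNC. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values of genes are from edgeR throughout, fold changes are log2 ratios with their standard errors (SE), and CPM are TMM-scaled means of 4 libraries with their SD. For YAP1 an exact two-sided permutation test of log2 CPM was run over the 70 assignments of 8 libraries to 2 groups of 4.

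Gene lists were compared with all other tested genes by camera (limma 3.58.1) on voom values, with the preset correlation of 0.01 between genes, adjusted over the 45 lists with at least 5 tested members, out of 47. The endothelial markers had 3 tested members and the markers of other nephron segments had 4, too few for the test. Of 1022 listed members 1012 were matched. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Members called within a list were counted with p-values adjusted over all genes and adjusted over the list alone. The samples, tests, lists and alternatives, and the rule for naming genes, were fixed before the data were examined. That rule took YAP1, a panel of 20 genes of senescence, the Hippo pathway and tubular injury, and, for the first 2 contrasts, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a clone or pseudogene name. It also took from each list up to 2 called members with the largest rise and up to 2 with the largest fall, at a mean of at least 1 CPM (for a list with no call, the 2 with the smallest p), and the 10 genes with the largest opposite changes and the 4 with the largest changes of 1 sign in the first 2 contrasts. For the third contrast the same genes were read. Some of these genes and 1 list are not reported here.

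The alternatives chosen beforehand were DESeq2 1.42.0 and limma-voom in place of edgeR, RLE factors, library sizes alone, scaling without mitochondrially encoded genes and the 20 most abundant genes, no low-count filter beyond 1 read in any library, a filter of 1 CPM in 4 libraries, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a change of at least 2-fold. Another 3 alternatives were added after seeing the data. One left out shNC replicate 4 and shYAP1_H2O2 replicate 3, which had a high share of mitochondrial counts. One took out, as an offset, the median log2 difference of the 51 genes around each gene on its chromosome. One corrected each library for transcript GC content and length with a smooth of span 0.3. Chromosome regions were described on chromosomes 1 to 22 and X as medians of genes with a mean of at least 5 CPM in 20 Mb windows with at least 15 such genes, set against 100 shuffles of gene positions.

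Because contrasts shared libraries, overlaps between them were set beside 20 simulated data sets of unchanged groups, beside the overlap of independent lists, and beside fits in which the shared libraries were split between the contrasts. The edgeR, limma and DESeq2 steps were tested on simulated data drawn from the means and library sizes of the real libraries, with 200 of 19268 genes changed. For shNC_H2O2 minus shNC, edgeR recovered 14% of genes changed 1.25-fold, 48% at 1.5-fold, 72% at 2-fold and 90% at 4-fold, with 5.08% of calls false, against 17.3% for DESeq2. For shYAP1_H2O2 minus shNC_H2O2 it recovered 6%, 52%, 70% and 98% at those sizes, with 8.13% of calls false, against 13.0% for DESeq2. Far more genes were called in the real data, so these shares do not give the recovery or false calls of the real comparisons. Exon overlaps were computed with bedtools 2.31.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures. Transcript isoforms, splicing and sequence variants were not analysed here.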

Results

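Polyadenylated RNA was counted per gene in 12 libraries of HK-2 cells, 4 in each of the groups shNC, shNC_H2O2 and shYAP1_H2O2. The series asks how the cells responded to 48 h of H2O2, and how that response differed in cells carrying a hairpin against YAP1, a transcriptional co-activator of the Hippo pathway. Total counts were 33509474, 43392575, 40016049 and 46582873 in shNC replicates 1 to 4, 37982539, 39102697, 30789997 and 41576669 in shNC_H2O2, and 37983702, 35485399, 37857464 and 46438941 in shYAP1_H2O2. Between 95.5% and 97.1% of counts fell on protein-coding genes. Values after ± are SD for CPM (n = 4 per group) and SE for log2 fold changes.

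The groups separated on the first principal component, which held 48.3% of the variance, with shNC_H2O2 at 65.0 to 67.0, shYAP1_H2O2 at -26.1 to -17.0 and shNC at -57.2 to -42.1. The second component, with 17.2%, set shYAP1_H2O2 (-45.4 to -34.1) apart from both other groups. The third, with 10.5%, was set by 2 libraries, shNC replicate 4 (-50.3) and shYAP1_H2O2 replicate 3 (-40.7). In these libraries 13.9% and 11.3% of counts came from mitochondrially encoded genes, against 4.54% to 5.64% in the other 10. Chi-square statistics per degree of freedom between replicates reached 156.4 to 180.6 in pairs with shNC replicate 4 and 108.6 to 133.4 in pairs with shYAP1_H2O2 replicate 3, against 2.96 to 6.99 in the remaining pairs. Both libraries stayed in their groups, and counts without them are given beside each comparison.

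**Figure D1:**
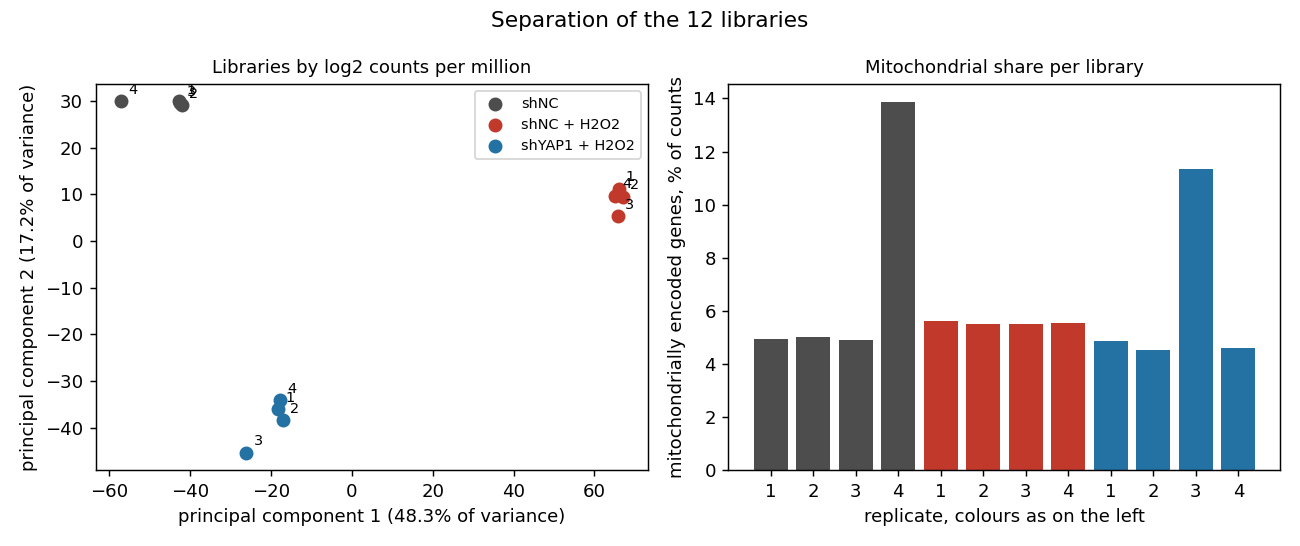
Left, the 12 libraries on the first 2 principal components of log2 CPM, which held 48.3% and 17.2% of the variance, coloured by group. Right, the percentage of counts from mitochondrially encoded genes per library, 13.9% in shNC replicate 4 and 11.3% in shYAP1_H2O2 replicate 3 against 4.54% to 5.64% in the other 10.

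YAP1 (ENSG00000137693, GRCh38 chromosome 11, 102110461 to 102233423) was read first in every library as a check of the knockdown labels. Its level was 135.9, 130.3, 140.5 and 123.7 CPM in shNC replicates 1 to 4, 155.2, 151.1, 155.6 and 163.5 CPM in shNC_H2O2, and 131.3, 134.7, 110.9 and 135.9 CPM in shYAP1_H2O2. The group means were 133 ± 7.25, 156 ± 5.19 and 128 ± 11.7 CPM. In the libraries labelled shYAP1_H2O2 it was 18% lower than in shNC_H2O2 (log2 fold change -0.29 ± 0.07, 95% interval -0.43 to -0.14, edgeR adjusted p = 0.00346, exact permutation p = 0.0286, the smallest the 70 permutations allow). With the shift of neighbouring genes removed, an alternative chosen after seeing the data, this difference was -0.18 and no longer passed (adjusted p = 0.0552). Against shNC the labelled knockdown libraries did not differ detectably in YAP1 (-0.05 ± 0.07, interval -0.20 to 0.10, adjusted p = 0.636, exact permutation p = 0.6). In shNC_H2O2 YAP1 was 17.9% higher than in shNC (0.24 ± 0.07, interval 0.09 to 0.39, adjusted p = 0.0104, exact permutation p = 0.0286). YAP1 mRNA was therefore lower in the labelled knockdown libraries only against shNC_H2O2, a comparison in which 8288 of 19268 genes were called. That difference alone does not establish a knockdown, and every direction given for the knockdown refers to libraries labelled shYAP1_H2O2.

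**Figure D2:**
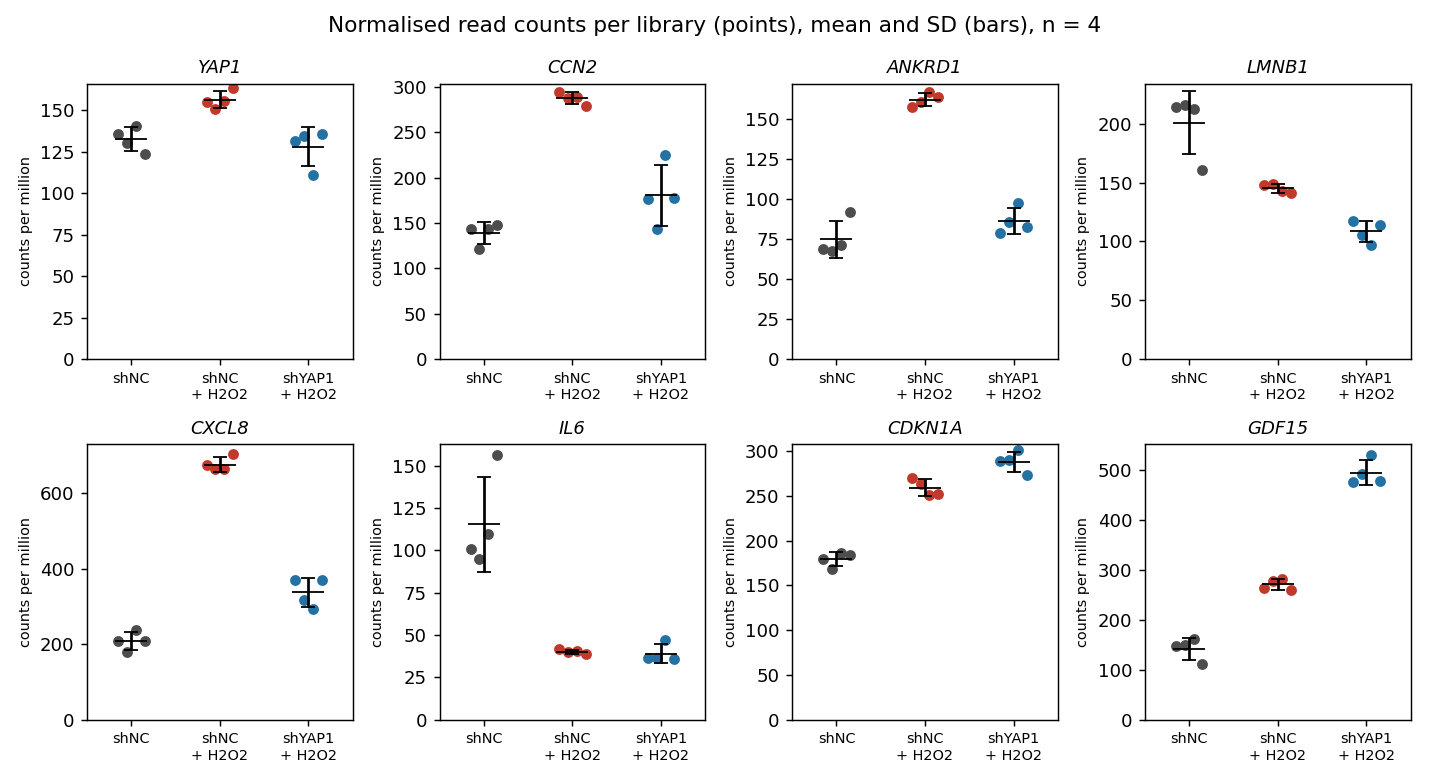
Levels of YAP1, CCN2, ANKRD1, LMNB1, CXCL8, IL6, CDKN1A and GDF15 in TMM-scaled CPM, with a point per library and the mean and SD of 4 libraries per group. YAP1 means were 133, 156 and 128 CPM in shNC, shNC_H2O2 and shYAP1_H2O2, and LMNB1 means 201, 145 and 108 CPM.

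The first comparison, shNC_H2O2 against shNC, concerns the response to H2O2. Changes with H2O2 are differences between these groups, which also differed by chromosome region, and the oxidant was not separated from other differences between the cultures. CXCL8, a neutrophil chemokine, rose from 208 ± 23.8 to 676 ± 18.9 CPM (1.70 ± 0.09, adjusted p = 4.7e-10). IL6, another cytokine of the senescent secretome, fell from 115 ± 28.1 to 40.2 ± 1.14 CPM (-1.52 ± 0.14, adjusted p = 3.5e-07). IL6 has 20.7% of its exon bases in an overlapping gene and is uncertain to that extent. The cyclin-dependent kinase inhibitor CDKN1A (p21) rose from 179 ± 7.74 to 259 ± 9.13 CPM (0.53 ± 0.06, adjusted p = 1.1e-06). CDKN2B rose (0.51 ± 0.11, adjusted p = 0.00142), and CDKN2A, which encodes p16, did not pass (-0.24 ± 0.13, adjusted p = 0.144). LMNB1, the lamin whose loss is used as a mark of senescence, fell from 201 ± 26.7 to 145 ± 3.67 CPM (-0.47 ± 0.09, adjusted p = 0.000417). Of 19268 tested genes 4612 were higher and 4359 lower, of which 1396 and 1253 changed at least 2-fold. Groups did not overlap for 48.0% of tested genes, against 2.86% by chance. Without the 2 libraries of high mitochondrial share 11603 genes were called.

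The largest rises with H2O2 were those of CDH13, a cadherin anchored in the membrane by a lipid (0.346 ± 0.182 to 53.6 ± 1.28 CPM, 7.22 ± 0.19), and ADAMTS5. SOX9, a transcription factor of tubular repair, rose too (6.17 ± 0.16), as did MMP13, a collagenase (2.09 ± 0.853 to 139 ± 3.10 CPM, 6.04 ± 0.19). They were followed by RFLNA, TBX3 and DOC2B. The largest falls were those of CLSTN2, a calsyntenin (948 ± 116 to 18.2 ± 0.61 CPM, -5.70 ± 0.11), ATOH8 (-5.56 ± 0.13), SLC34A2, a phosphate transporter (-5.25 ± 0.40), and LINC02532, then RSPO3, QRFPR, SHOC1 and UCA1. Adjusted p-values of these 15 genes lay between 1.3e-14 and 3.8e-06.

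GDF15, a stress cytokine, rose from 142 ± 21.6 to 271 ± 10.8 CPM (0.93 ± 0.09), and by 0.55 with neighbouring genes' shift removed. Of 25 secreted senescence-associated factors 12 were higher, 9 lower and 4 not called (13 and 9 adjusted over the list alone). MMP1 (3.89 ± 0.09) and IL11 (2.77 ± 0.09) rose while AREG (-3.56 ± 0.10) and CXCL5 (-2.32 ± 0.16) fell, and the set did not pass (adjusted p = 0.0762), but passed without the 2 libraries of high mitochondrial share (0.0269). Among 10 inhibitors of cyclin-dependent kinases and RB family genes 2 were higher and 2 lower, the same adjusted over the list alone (set adjusted p = 0.776), and 2 and 4 without the 2 libraries of high mitochondrial share. CDKN1C was among those that fell (-1.40 ± 0.10).

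Genes of mitosis fell together with H2O2, 21 of 35 lower and 0 higher (21 and 0 adjusted over the list alone), among them the kinases AURKA (-0.84 ± 0.09) and PLK1 (-0.79 ± 0.14). The set had a median of -0.27 (adjusted p = 8.1e-06, adjusted p = 0.149 with an estimated correlation), and 20 were lower and 3 higher with the shift of neighbouring genes removed. MKI67, the proliferation antigen, went from 400 ± 44.8 to 309 ± 5.47 CPM (-0.37 ± 0.14, adjusted p = 0.0394). That call was lost without shNC replicate 2 (adjusted p = 0.0591) or 4 (0.133), and without shNC_H2O2 replicate 1, 2, 3 or 4 (0.0698, 0.0717, 0.0830 and 0.0772). Of 35 DNA replication genes 17 were lower and 3 higher (18 and 3 adjusted over the list alone), with a median of -0.21. The helicase subunit MCM2 (-0.69 ± 0.10, -0.02 with neighbouring genes' shift removed, overlapping) and RFC4 (-0.71 ± 0.08, then -0.21) lie on the shifted part of chromosome 3 described with the chromosome regions. That set passed too (adjusted p = 0.00606, adjusted p = 0.541 with an estimated correlation). Recombination and Fanconi repair genes did not pass as a set (3 higher and 6 lower of 25, 1 and 4 adjusted over the list alone, adjusted p = 0.419), with 5 higher and 11 lower without the 2 libraries of high mitochondrial share.

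Antioxidant genes were mostly lower after the 48 h. Of 27 tested targets of NRF2, the main regulator of the antioxidant response, 16 were lower and 3 higher, the same adjusted over the list alone, with a median of -0.54. HMOX1, heme oxygenase 1, fell from 31.6 ± 2.37 to 11.9 ± 0.686 CPM (-1.41 ± 0.09, adjusted p = 2.9e-09), and NQO1 (-0.99 ± 0.07) and PIR (-1.62 ± 0.14) fell, whereas TXNRD1, thioredoxin reductase, rose (0.39 ± 0.10). The set passed (adjusted p = 0.000581, adjusted p = 0.113 with an estimated correlation). Of 26 other antioxidant enzymes 14 were lower and 3 higher (the same adjusted over the list alone). MGST1 (-2.16 ± 0.32) and SOD2 (-2.17 ± 0.12, with 6.93% of its exon bases in another gene) were lower and MSRB3 higher (1.5 ± 0.09). Their set gave an adjusted p = 0.00606, and an adjusted p = 0.149 with an estimated correlation. Ferroptosis genes were lower in 12 of 22 and higher in 2 (13 and 2 adjusted over the list alone), with PTGS2 lower (-3.44 ± 0.37) and STEAP3 higher (0.95 ± 0.07). Their set passed (adjusted p = 0.00606, adjusted p = 0.149 with an estimated correlation).

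In camera at the preset correlation glycolysis genes showed the smallest set p of this comparison, but not with an estimated correlation or in fry. Of 19 members 14 were lower and 1 higher (the same adjusted over the list alone), with a median of -0.77 (camera adjusted p = 7.0e-07, adjusted p = 0.159 with an estimated correlation). LDHA, lactate dehydrogenase, fell (-1.82 ± 0.10), as did ALDOA (-2.15 ± 0.41), which shares 53.5% of its exon bases with another gene. Genes of the hypoxia response were lower in 12 of 20 and higher in 2 (13 and 2 adjusted over the list alone, adjusted p = 0.000135, adjusted p = 0.149 with an estimated correlation). EGLN3 (-2.41 ± 0.16) and the carbonic anhydrase CA9 (-3.81 ± 0.31, overlapping) fell, and VEGFA rose (0.28 ± 0.06). Nuclear-encoded genes of oxidative phosphorylation were lower in 14 of 28 and higher in 1, the same adjusted over the list alone (adjusted p = 0.00497, adjusted p = 0.402 with an estimated correlation), with ATP5MC1 at -1.12 ± 0.08. Of 14 fatty acid synthesis genes 9 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.0163, adjusted p = 0.196 with an estimated correlation). The desaturase SCD (-0.89 ± 0.07) and its regulator SREBF1 (-0.88 ± 0.09) fell. Antigen presentation and complement genes were lower in 9 of 19 and higher in 1 (the same adjusted over the list alone, adjusted p = 0.00606, adjusted p = 0.196 with an estimated correlation), led by C3 (-2.49 ± 0.09) and C1S (-2.43 ± 0.11).

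Several groups of signalling genes rose with H2O2. WNT and NOTCH targets were higher in 14 of 20 and lower in 2, the same adjusted over the list alone, with a median of 0.96 (adjusted p = 0.000191, adjusted p = 0.113 with an estimated correlation). The NOTCH ligand JAG1 (2.95 ± 0.09) and NRARP (2.96 ± 0.12) rose, and the receptor NOTCH3 fell (-0.98 ± 0.11). TGF-beta response genes were higher in 12 of 20 and lower in 6 (the same adjusted over the list alone), with a median of 0.81. The activin subunit INHBA (4.76 ± 0.08) and LTBP2 (2.71 ± 0.07) rose, and ID3 (-2.71 ± 0.15) and BMP4 (-2.28 ± 0.30), which belong to the BMP branch, fell. That set passed (adjusted p = 0.0312, adjusted p = 0.316 with an estimated correlation) but not with library sizes alone (0.0657). Immediate-early genes rose in 15 of 26 and fell in 3, the same adjusted over the list alone (adjusted p = 0.000581, adjusted p = 0.394 with an estimated correlation), among them EGR3 (2.69 ± 0.31) and KLF2 (2.14 ± 0.15). Genes of the integrated stress response were higher in 14 of 27 and lower in 4, the same adjusted over the list alone (adjusted p = 0.0226, adjusted p = 0.541 with an estimated correlation), led by ATF3 (1.29 ± 0.10).

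Targets of YAP and TAZ with TEAD did not pass as a set against other genes with H2O2 (8 of 22 higher and 6 lower, the same adjusted over the list alone, adjusted p = 0.419), whereas fry, which tests the set by itself, called it higher (adjusted p = 0.00914). The split was 13 and 6 without the 2 libraries of high mitochondrial share, and the set again did not pass (adjusted p = 0.257). CCN2 rose from 139 ± 11.9 to 288 ± 6.61 CPM (1.05 ± 0.11, adjusted p = 7.0e-07) and ANKRD1 from 75 ± 11.5 to 162 ± 4 CPM (1.12 ± 0.09, adjusted p = 9.4e-08). CCN1 fell from 1807 ± 128 to 1392 ± 33.7 CPM (-0.38 ± 0.06, adjusted p = 8.7e-05). NT5E rose (1.77 ± 0.08) and FJX1 fell (-0.74 ± 0.09). Of 20 Hippo pathway components 8 were higher and 6 lower (the same adjusted over the list alone, set adjusted p = 0.776), with AMOT at 0.84 ± 0.08 and WWC1 at -1.30 ± 0.05. They were split 12 and 7 without the 2 libraries and 6 and 3 with the shift of neighbouring genes removed. WWTR1, which encodes TAZ and lies on the shifted part of chromosome 3, was at -0.44 ± 0.07, and at 0.23 with neighbouring genes' shift removed. TEAD1 did not pass (0.02 ± 0.10, adjusted p = 0.860). The injury marker HAVCR1 (KIM-1) fell from 380 ± 81.7 to 78.5 ± 2.04 CPM (-2.27 ± 0.14, adjusted p = 4.3e-09) and LCN2 fell (-1.71 ± 0.30), while SOX9 and KRT7 (3.60 ± 0.15) rose. Tubular injury genes were higher in 8 and lower in 11 of 24, the same adjusted over the list alone (adjusted p = 0.776, with a mean of 0.08 against a median of -0.02). No list passed with an estimated correlation in this comparison. Camera then gave 0 of 45 lists, with 11 at an unadjusted p under 0.05, where fry called 32.

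Changes in shNC_H2O2 also followed chromosome position, a pattern looked for only after the data had been seen. Genes of chromosome 3 from 81489699 to 198222513 (GRCh38) had a median log2 fold change of -0.59 against shNC, with 89.7% of 348 genes lower. The medians were -0.54 on chromosome 1 from 144421386 to 180114880 (248 genes), -0.44 on chromosome 4 from 53285 to 18021876 (81 genes) and 0.46 on chromosome 21 from 25561909 to 46665124 (101 genes). In the libraries labelled shYAP1_H2O2, which also received H2O2, the medians of these regions against shNC were -0.01, 0.02, 0.01 and 0.03. Of 153 windows of 20 Mb, 11 lay beyond every one of 100 shuffles of gene positions in shNC_H2O2 against shNC and 17 in shYAP1_H2O2 against shNC_H2O2, and 0 did so in shYAP1_H2O2 against shNC, where the largest absolute median was 0.165. The largest shuffled medians differed, at 0.393, 0.319 and 0.316 in that order, so 11 and 17 do not rank the comparisons. The largest absolute medians of the first 2 were 0.736 and 0.666. Per library, the median of chromosome 3 was -0.342 to -0.332 in shNC_H2O2, against -0.0238 to 0.0506 in shNC and -0.0375 to 0.0419 in shYAP1_H2O2. A single limit served for windows of few and of many genes, so it does not mark where a shift ends. On chromosome 1 the windows from 180154834, 200404940 and 220057482 still had medians of -0.3885, -0.3265 and -0.2583 in shNC_H2O2 against shNC. The window of chromosome 3 from 61561569 had -0.2804 (86.7% of 30 genes lower). Smaller shifts, with no window beyond every shuffle in shNC_H2O2 against shNC, ran over chromosomes 19 (median 0.30, 788 genes, 19.0% lower), 14 (0.24, 381 genes, 22.3% lower), 2 (0.19, 768 genes, 29.4% lower) and 22 (-0.14, 261 genes, 62.5% lower). On the 15 chromosomes with an absolute median under 0.1, 50.4% of 6880 genes were called in shNC_H2O2 against shNC, and 60.3% of 4612 on the other 8, which were chromosomes 1, 2, 3, 4, 14, 19, 21 and 22. These counts cover genes with a mean of at least 5 CPM. The 15 chromosomes still held shifted windows, such as chromosome 16 from 80597906 (median -0.31, 85.3% of 68 genes lower). On chromosome 5 the windows from 196871 and from 21341833 had medians of 0.24 and 0.25. With the shift of the 51 genes around each gene removed, 8108 genes were called, 7021 of them shared with the 8971. CLSTN2 lies in the chromosome 3 region (139935185 to 140577397) and kept a fold change of -5.01, and ADAMTS5 and MX1 lie in that of chromosome 21.

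**Figure D3:**
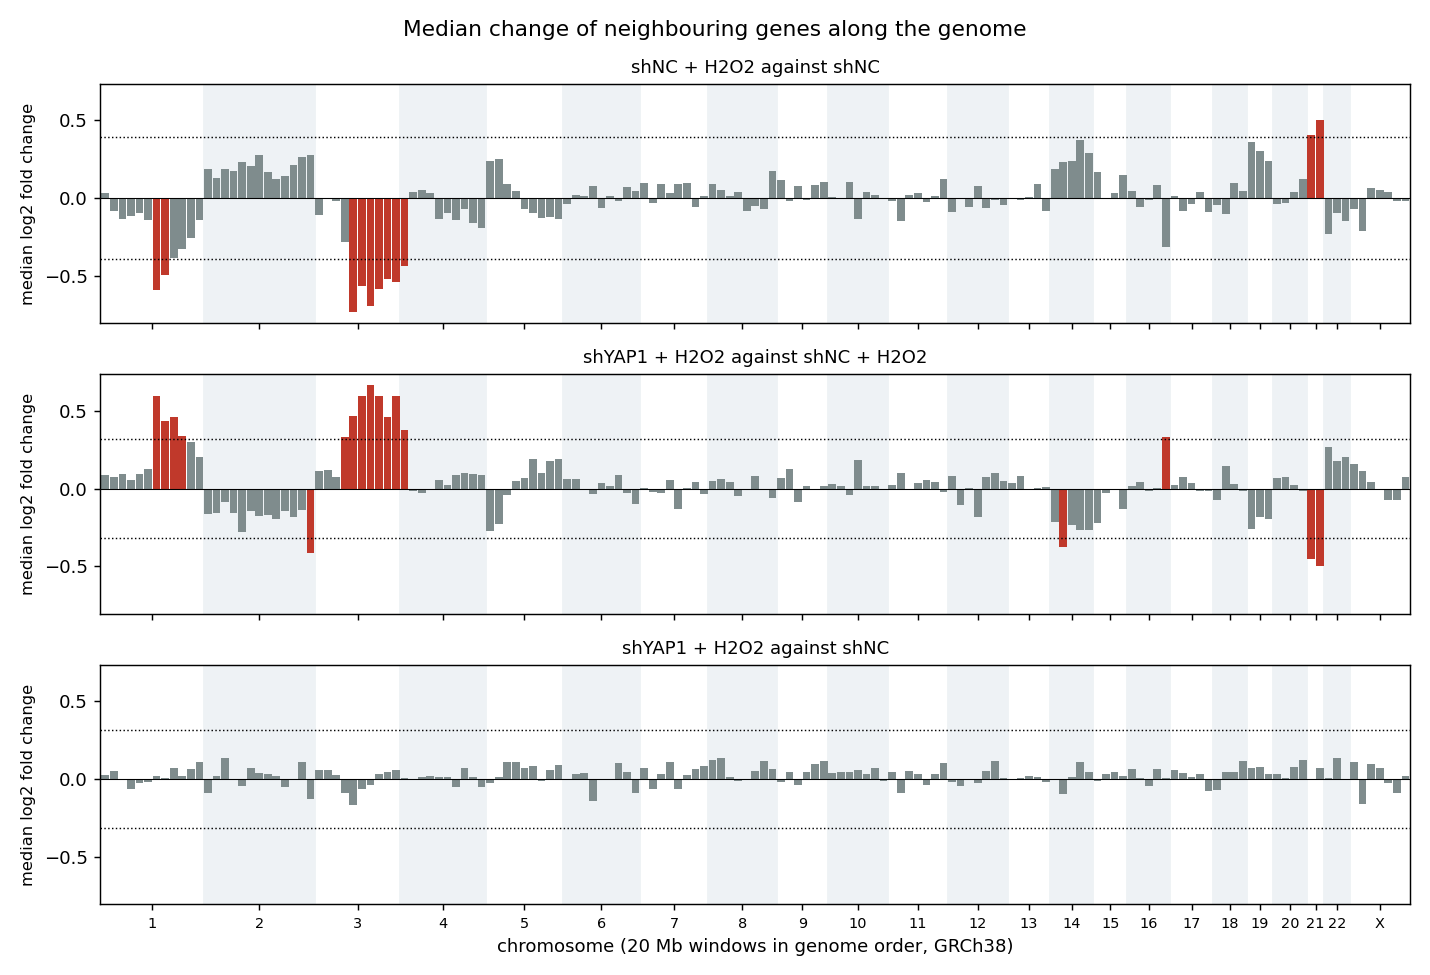
Median log2 fold change of the genes in each of 153 windows of 20 Mb along chromosomes 1 to 22 and X for the 3 comparisons, with dotted lines at the largest median of 100 shuffles and windows beyond it in red. Such windows numbered 11, 17 and 0 in shNC_H2O2 minus shNC, shYAP1_H2O2 minus shNC_H2O2 and shYAP1_H2O2 minus shNC. The lines lie at 0.393, 0.319 and 0.316 in that order.

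The second comparison, shYAP1_H2O2 against shNC_H2O2, concerns the hairpin in cells given H2O2. These groups also differed by chromosome region, and the hairpin was not separated from that or from other differences between the cultures. CXCL8 was lower in the labelled knockdown libraries, at 338 ± 38 CPM (-1.0 ± 0.09, adjusted p = 2.4e-07). IL6, at 39.1 ± 5.43 CPM, did not pass (-0.04 ± 0.14, adjusted p = 0.83). GDF15 was higher, at 495 ± 25 CPM (0.87 ± 0.09, adjusted p = 1.5e-06), and LMNB1 was lower again, at 108 ± 9.12 CPM (-0.42 ± 0.09, adjusted p = 0.00124). CDKN1A was at 288 ± 11.2 CPM (0.15 ± 0.06, adjusted p = 0.0354). Its call was lost with library sizes alone (0.232) and without shNC_H2O2 replicate 2 (0.0623), 3 (0.0963) or 4 (0.103) or shYAP1_H2O2 replicate 1 (0.0696) or 2 (0.0666). CDKN2A (0.01 ± 0.13, adjusted p = 0.956) and CDKN2B (-0.26 ± 0.11, adjusted p = 0.0750) did not pass. Without the 2 libraries of high mitochondrial share CDKN2A was at -0.17 (adjusted p = 0.000195). Of 19268 genes 4235 were higher and 4053 lower, 977 and 1082 of them at least 2-fold, and groups did not overlap for 45.2%. The count was 11194 without the 2 libraries of high mitochondrial share and 7371 with the shift of neighbouring genes removed.

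Targets of YAP and TAZ with TEAD, the genes on which YAP1 acts through its DNA-binding partners, were lower in 9 and higher in 9 of 22 (9 and 9 adjusted over the list alone), and the set did not pass (adjusted p = 0.677). CCN2 was lower, at 181 ± 33.5 CPM (-0.67 ± 0.10, adjusted p = 8.6e-05), as were ANKRD1, at 86.3 ± 8.24 CPM (-0.91 ± 0.09, adjusted p = 1.2e-06), NT5E (-1.77 ± 0.08) and CCDC80 (-1.19 ± 0.08). F3, which encodes tissue factor, was higher (1.19 ± 0.08), and so was TGFB2 (0.99 ± 0.16), which overlaps another gene. CCN1, at 1595 ± 22.9 CPM, was also higher (0.20 ± 0.06, adjusted p = 0.0149), but not with library sizes alone (0.190) or with the shift of neighbouring genes removed (0.0600). TEAD1 was lower (-0.33 ± 0.10, adjusted p = 0.0134). Hippo components were split 6 and 6 over 20 (7 higher and 6 lower adjusted over the list alone, set adjusted p = 0.611).

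The largest falls in this comparison were those of MMP13 (to 1.43 ± 0.28 CPM, -6.62 ± 0.20), CDH13 (to 0.556 ± 0.0624 CPM, -6.58 ± 0.18), RFLNA, ADAMTS5 and MMP1, an interstitial collagenase (-5.25 ± 0.10), then CAMK1D and THBS2. The largest rises were those of CLSTN2 (to 454 ± 50.8 CPM, 4.64 ± 0.10, and 3.96 with neighbouring genes' shift removed), ADCY8, an adenylate cyclase (4.13 ± 0.16), QRFPR and RSPO3, then EPHA5, SLC34A2, CRYAB, which overlaps another gene, and PTCHD1. Adjusted p-values of these 15 genes lay between 1.2e-14 and 1.2e-05.

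Extracellular matrix genes were lower in 15 of 28 and higher in 7, the same adjusted over the list alone, with a median of -0.38. FN1, fibronectin, fell from 20985 ± 1365 to 10224 ± 1861 CPM (-1.04 ± 0.12, adjusted p = 3.7e-06), FBN1 (-2.68 ± 0.07) and MMP2 (-2.13 ± 0.22) fell, and ELN (2.10 ± 0.20) and COL6A3 (1.86 ± 0.19) rose. The set passed (adjusted p = 0.0188, adjusted p = 0.339 with an estimated correlation). TGF-beta response genes were lower in 11 of 20 and higher in 5 (12 and 5 adjusted over the list alone, adjusted p = 0.00790, adjusted p = 0.273 with an estimated correlation). INHBA (-3.66 ± 0.07) and LTBP2 (-2.67 ± 0.07) fell, and BMP4 (3.11 ± 0.30) and BAMBI, a decoy receptor (2.78 ± 0.16), rose. WNT and NOTCH targets were lower in 11 of 20 and higher in 4 (11 and 5 adjusted over the list alone, adjusted p = 0.0195, adjusted p = 0.273 with an estimated correlation). NOTUM was among the former (-2.31 ± 0.20) and JAG1 among the latter (0.42 ± 0.09). Epithelial junction genes were higher in 12 of 21 and lower in 3 (12 and 4 adjusted over the list alone, adjusted p = 0.0106, adjusted p = 0.273 with an estimated correlation). The desmosomal cadherin DSC2 (2.46 ± 0.09) and the splicing regulator ESRP1 (1.94 ± 0.14) rose and CLDN2 fell (-1.83 ± 0.15). Secreted senescence-associated factors were lower in 11 and higher in 6 of 25 (11 and 7 adjusted over the list alone, set adjusted p = 0.106, and 0.0275 without the 2 libraries), with IGFBP5 at -2.73 ± 0.13 and AREG at 2.47 ± 0.10.

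Chaperones rose in the labelled knockdown libraries. Of 20 chaperones of the endoplasmic reticulum 14 were higher and 0 lower, the same adjusted over the list alone, with a median of 0.54 (adjusted p = 3.6e-05, adjusted p = 0.273 with an estimated correlation). HSPA5, which encodes BiP, rose from 1485 ± 7.91 to 2834 ± 565 CPM (0.93 ± 0.12, adjusted p = 1.3e-05), and HERPUD1 rose (0.74 ± 0.07). Heat shock proteins were higher in 10 of 17 and lower in 0, the same adjusted over the list alone (adjusted p = 0.00174, adjusted p = 0.125 with an estimated correlation). HSPB8 (0.95 ± 0.08) and HSPA1A, a near copy of HSPA1B (0.69 ± 0.08), rose. Integrated stress response genes were higher in 11 of 27 and lower in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.0186, adjusted p = 0.412 with an estimated correlation). CTH (1.39 ± 0.13) and DDIT3, which encodes CHOP and overlaps another gene (1.09 ± 0.12), rose. In the absence of the 2 libraries of high mitochondrial share 17 of that list were higher and 2 lower. NF-kB feedback genes were higher in 10 of 18 and lower in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00387, adjusted p = 0.339 with an estimated correlation), led by TNFAIP3, the inhibitor A20 (2.24 ± 0.08), and in 11 and 3 without the 2 libraries or with the shift of neighbouring genes removed.

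Several sets of metabolic and antioxidant genes were higher than other genes against shNC_H2O2. Fatty acid synthesis (3 higher and 5 lower of 14, the same adjusted over the list alone, adjusted p = 0.366) and cholesterol synthesis (3 and 5 of 23, 2 and 4 adjusted over the list alone, adjusted p = 0.83) did not pass. Their counts were 4 and 8, and 6 and 7, without the 2 libraries of high mitochondrial share. Glycolysis genes were higher in 14 of 19 and lower in 1, the same adjusted over the list alone (adjusted p = 0.000643, adjusted p = 0.339 with an estimated correlation), with hexokinase HK2 at 1.33 ± 0.09. Hypoxia genes were higher in 12 of 20 and lower in 0, the same adjusted over the list alone (adjusted p = 0.000549, adjusted p = 0.273 with an estimated correlation), with CA12 at 2.54 ± 0.14 and NDRG1 at 1.63 ± 0.07. HMOX1 rose to 23.3 ± 2.22 CPM (0.97 ± 0.09), and NQO1 rose (0.36 ± 0.07). Of 27 NRF2 targets 12 were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.0195, adjusted p = 0.273 with an estimated correlation). Ferroptosis genes, 11 of 22 higher and 3 lower (12 and 3 adjusted over the list alone), gave an adjusted p = 0.0195 (adjusted p = 0.273 with an estimated correlation), with PTGS2 at 3.66 ± 0.37. Lysosome and autophagy genes were higher in 18 of 29 and lower in 3, the same adjusted over the list alone (adjusted p = 0.0188, adjusted p = 0.273 with an estimated correlation), NEU1 among them (0.80 ± 0.06). That call was lost with the shift of neighbouring genes removed (0.0518, 11 higher and 3 lower), and 18 were higher and 8 lower without the 2 libraries of high mitochondrial share. Ribosomal proteins, which have many near-identical copies, were higher in 14 of 26 and lower in 1, the same adjusted over the list alone (adjusted p = 0.0151, adjusted p = 0.494 with an estimated correlation), and in 22 and 3 without the 2 libraries of high mitochondrial share. Ribosome biogenesis genes were higher in 15 of 24 and lower in 5 (16 and 6 adjusted over the list alone, adjusted p = 0.0195, adjusted p = 0.339 with an estimated correlation), with NME1 at 0.76 ± 0.14, and in 14 and 1 with the shift of neighbouring genes removed.

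Another 3 sets passed narrowly against shNC_H2O2. Other antioxidant enzymes were higher in 13 of 26 and lower in 2, the same adjusted over the list alone (adjusted p = 0.0414, adjusted p = 0.295 with an estimated correlation), with GPX3 at 1.71 ± 0.18. That call was lost with library sizes alone (0.0621), the stricter filter (0.0633), the shift of neighbouring genes removed (0.0637), GC and length corrected (0.0685) and without both libraries of high mitochondrial share (0.0563, 14 higher and 8 lower). It was also lost without shNC_H2O2 replicate 3 (0.0533) or shYAP1_H2O2 replicate 3 (0.0862). Antigen presentation and complement genes were higher in 8 of 19 and lower in 0, the same adjusted over the list alone (adjusted p = 0.0482, adjusted p = 0.339 with an estimated correlation), C3 among them (1.83 ± 0.09). Their call was lost without shNC replicate 3 (0.0506) or 4 (0.0680), shNC_H2O2 replicate 4 (0.0535), or shYAP1_H2O2 replicate 1 (0.0515) or 4 (0.0668). It was also lost with the stricter filter (0.0515), the 2 groups alone (0.0774), GC and length corrected (0.0771) or the shift of neighbouring genes removed (0.130, 6 higher and 3 lower), and 11 were higher and 3 lower without the 2 libraries. Nuclear-encoded genes of oxidative phosphorylation were higher in 11 of 28 and lower in 1, the same adjusted over the list alone (adjusted p = 0.0279, adjusted p = 0.459 with an estimated correlation), with ATP5MC1 at 0.74 ± 0.08, and 18 were higher and 2 lower without the 2 libraries. That call was lost without shYAP1_H2O2 replicate 4 (0.0718), with the stricter filter (0.0515) and with GC and length corrected (0.0771). DNA replication genes did not pass (14 lower and 5 higher of 35, 15 and 5 adjusted over the list alone, adjusted p = 0.102). Mitosis genes were lower in 12 and higher in 4 of 35, the same adjusted over the list alone (adjusted p = 0.127), and DNA repair genes lower in 10 and higher in 3 of 25 (11 and 3 adjusted over the list alone, adjusted p = 0.113). These 3 sets passed as lower with the shift of neighbouring genes removed (adjusted p = 0.00881 for replication, 0.0156 for mitosis and 0.0194 for repair, with 16, 15 and 10 lower and 1 higher in each), and replication (0.0256, 21 lower and 8 higher) and mitosis (0.0334, 18 and 5) also did without the 2 libraries. With an estimated correlation 0 of 45 lists passed in camera, 7 of them at an unadjusted p under 0.05, where fry called 36.

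**Figure D4:**
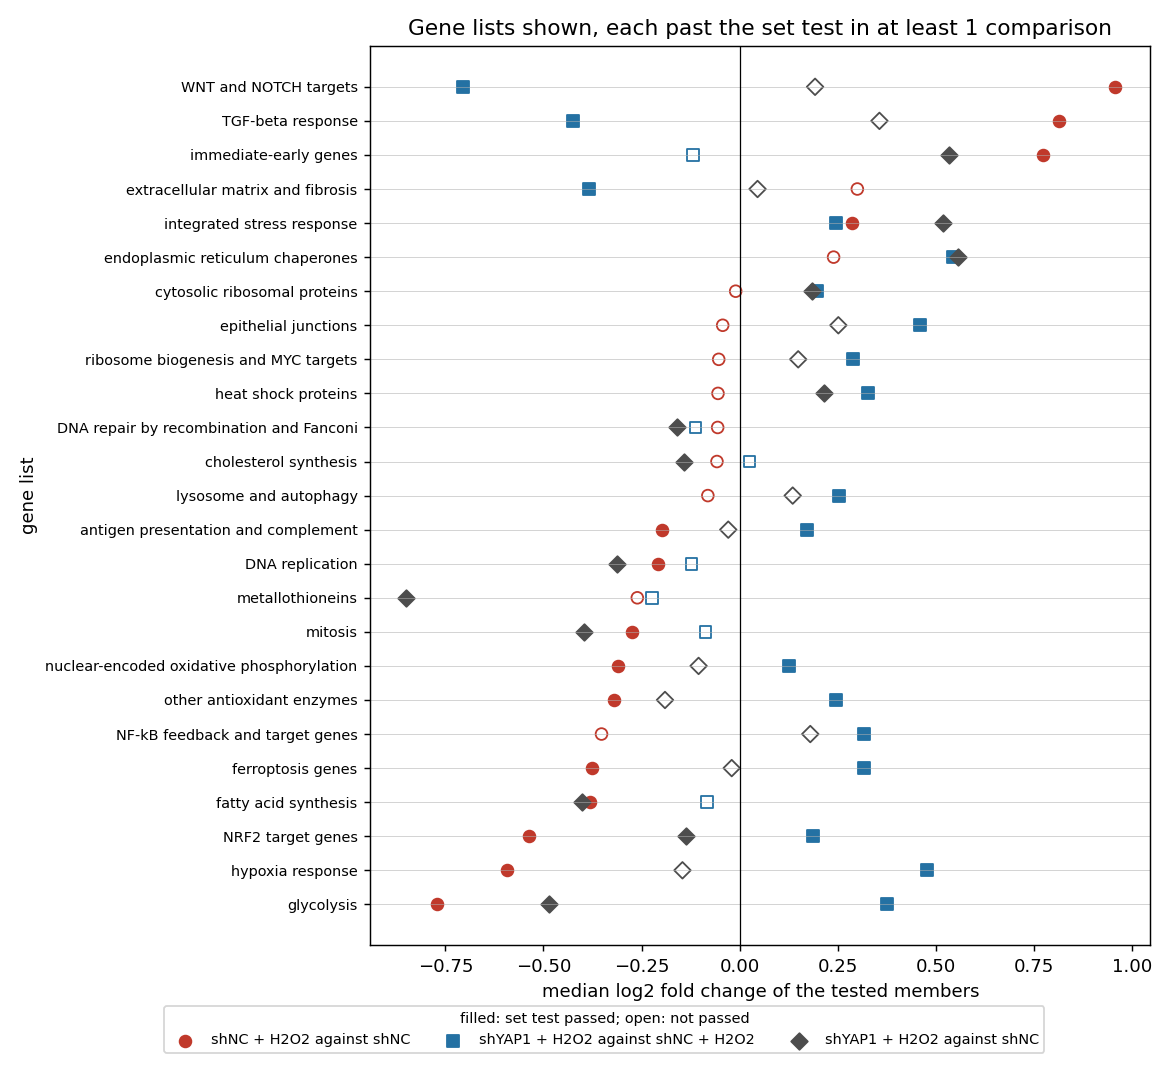
Median log2 fold change of the tested members of each gene list shown that passed camera in at least 1 comparison, by comparison, with filled points where the list passed (adjusted p under 0.05) and open points where it did not. Glycolysis medians were -0.77, 0.38 and -0.49 in shNC_H2O2 minus shNC, shYAP1_H2O2 minus shNC_H2O2 and shYAP1_H2O2 minus shNC.

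Against untreated shNC cells, the libraries labelled shYAP1_H2O2 had higher CXCL8 (0.70 ± 0.09, adjusted p = 2.0e-05) and CDKN1A (0.68 ± 0.06, adjusted p = 2.2e-07). GDF15 was higher too (1.80 ± 0.09, adjusted p = 2.3e-09). IL6 (-1.56 ± 0.14, adjusted p = 8.1e-07) and LMNB1 (-0.89 ± 0.09, adjusted p = 2.0e-06) were lower. CCN2 was higher (0.38 ± 0.10, adjusted p = 0.0111), ANKRD1 did not pass (0.20 ± 0.09, adjusted p = 0.111), and HAVCR1, at 205 ± 35 CPM, was lower (-0.89 ± 0.13, adjusted p = 0.000123). In all 3362 genes were higher and 2903 lower, 625 and 494 of them at least 2-fold, with groups that did not overlap for 29.7%. The count was 9146 without the 2 libraries of high mitochondrial share. Since both the hairpin and the oxidant differ between these groups, neither can be given as the source of a change.

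Mitosis genes were lower in 26 of 35 and higher in 0 (28 and 0 adjusted over the list alone), with a median of -0.40 (adjusted p = 3.9e-12), including AURKA (-0.79 ± 0.09) and the motor KIF11 (-0.55 ± 0.05). DNA replication genes were lower in 24 of 35 and higher in 1 (27 and 1 adjusted over the list alone, adjusted p = 1.9e-08, adjusted p = 0.202 with an estimated correlation), with UHRF1 at -0.87 ± 0.13. DNA repair genes were lower in 10 of 25 and higher in 0 (10 and 1 adjusted over the list alone, adjusted p = 0.00452, adjusted p = 0.132 with an estimated correlation), with BRIP1 at -0.47 ± 0.08. Chaperones of the endoplasmic reticulum were higher in 15 of 20 and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 3.1e-08, adjusted p = 0.166 with an estimated correlation), HSPA5 by 1.60 ± 0.12 and HERPUD1 by 1.22 ± 0.08. Integrated stress response genes were higher in 19 of 27 and lower in 0 (19 and 1 adjusted over the list alone, adjusted p = 1.9e-08, adjusted p = 0.161 with an estimated correlation), with CTH at 1.57 ± 0.13. Heat shock proteins were higher in 7 of 17 and lower in 0 (10 and 0 adjusted over the list alone, adjusted p = 0.000678), with DNAJB1 at 0.79 ± 0.07, and in 14 and 1 without the 2 libraries of high mitochondrial share. Fatty acid synthesis genes were lower in 10 of 14 and higher in 0 (11 and 0 adjusted over the list alone, adjusted p = 5.3e-07), with SCD at -0.78 ± 0.07. Mitosis, heat shock and fatty acid synthesis were the 3 lists whose call held with an estimated correlation, each at an adjusted p = 0.0395.

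Immediate-early genes were higher in 13 of 26 and lower in 1 (15 and 1 adjusted over the list alone, adjusted p = 8.0e-05, adjusted p = 0.336 with an estimated correlation), with 13 and 6 without the 2 libraries. Glycolysis genes were lower in 13 of 19 and higher in 2, the same adjusted over the list alone (adjusted p = 7.0e-05, adjusted p = 0.292 with an estimated correlation), with LDHA at -1.10 ± 0.10 and HK2 at 1.23 ± 0.08. NRF2 targets were lower in 11 of 27 and higher in 2 (11 and 3 adjusted over the list alone, adjusted p = 0.0262, adjusted p = 0.166 with an estimated correlation), with NQO1 at -0.63 ± 0.07 and HMOX1 at -0.44 ± 0.08, and 14 were lower and 4 higher without the 2 libraries. Ribosomal proteins were higher in 9 of 26 and lower in 0 (10 and 0 adjusted over the list alone, adjusted p = 0.000601, adjusted p = 0.386 with an estimated correlation). Their count was 20 without the 2 libraries of high mitochondrial share and 6 with the shift of neighbouring genes removed. Cholesterol synthesis genes were lower in 8 of 23 and higher in 3, the same adjusted over the list alone (adjusted p = 0.0378, adjusted p = 0.386 with an estimated correlation). Without the 2 libraries 14 were lower and 5 higher. That call was lost with library sizes alone (0.0709), with the replicate number as a block (0.0502), and without shNC replicate 1 (0.0602) or 3 (0.0597) or shYAP1_H2O2 replicate 2 (0.0634). Metallothioneins, with near-identical copies, were lower in 3 of 7 and higher in 0 (4 and 0 adjusted over the list alone, adjusted p = 0.0364, adjusted p = 0.478 with an estimated correlation), MT1E at -1.33 ± 0.23. That call was lost without shNC replicate 4 (0.137) or shYAP1_H2O2 replicate 1 (0.0547), with the shift of neighbouring genes removed (0.0620) and with GC and length corrected (0.0941). The YAP and TAZ targets again did not pass (8 of 22 higher and 6 lower, 9 and 6 adjusted over the list alone, adjusted p = 0.522).

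Most genes called between shNC_H2O2 and shNC differed the opposite way between the libraries labelled shYAP1_H2O2 and shNC_H2O2. CXCL8, CCN2, ANKRD1 and FN1 were highest in shNC_H2O2, and HMOX1 and HAVCR1 lowest. GDF15 rose in both comparisons, while LMNB1 and ID1, an inhibitor of DNA binding (-1.90 ± 0.14 and -1.09 ± 0.14), fell in both. Of the genes called in both, 5349 went opposite ways, 2697 up and then down and 2652 down and then up, where independent lists would share 970 and 958, and 355 went the same way. The latter were 555 without shNC replicate 4 and 1049 without the 2 libraries of high mitochondrial share (7451 opposite, or 87.7% against 93.8%). Both comparisons use the 4 shNC_H2O2 libraries with opposite sign, which by itself favours opposite directions. With unchanged groups simulated on shared libraries edgeR called 0 genes in both (194.2 on average went opposite ways and 1.5 the same way at an unadjusted p under 0.05). The correlation of fold changes across genes, which are not independent replicates, was -0.782 (covariance -0.538), against -0.503 (-0.0285) in the simulations. With the shNC_H2O2 libraries split 2 and 2 between the comparisons, in 6 ways, 3824 to 3917 genes went opposite ways and 164 to 246 the same way, with a correlation of -0.725 to -0.698 and a covariance of -0.533 to -0.521. Such a split takes out noise of single libraries, but not a difference that all 4 shNC_H2O2 libraries share. Of the 5349 genes 3562 (66.6%) were not called against shNC, 1217 differed from shNC in the same direction as shNC_H2O2, and 570 lay past the shNC level.

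Many genes differed from shNC in the same direction in both groups given H2O2. Of genes called in both, 3537 moved the same way (1898 higher and 1639 lower, where independent lists would share 805 and 657) and 570 the opposite way. The correlation across genes was 0.518 (covariance 0.259), against 0.497 (0.0280) in simulations of unchanged groups that shared the shNC libraries, so the correlation by itself lay close to that without any change. Splitting the shNC libraries 2 and 2 left 2443 to 2648 genes moved the same way, with a correlation of 0.374 to 0.429 and a covariance of 0.210 to 0.240. A difference common to all shNC libraries would stay in these splits. JAG1 (2.95 ± 0.09 and 3.38 ± 0.09), SOX9 (3.52 ± 0.16 in shYAP1_H2O2), and AMOT (0.84 ± 0.08 and 0.82 ± 0.08) were among genes higher in both, and ATOH8 (-3.27 ± 0.11 in shYAP1_H2O2) among those lower in both.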

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

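The tests with shuffled gene positions, with the labelled knockdown libraries, with terciles of expression, of a swap, of a correlation between the 2 libraries that stood apart, of GC and length bias in single libraries and of the opposite directions were chosen only after the result was seen, while those of GC and length bias in the regions, of mitochondrial transcripts and of other splits of the libraries were chosen before it.

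In groups of 4 libraries a library was singled out where its gap to the nearest of the others exceeded the 95% limit of Dixon's ratio of gap to range. Chance singles out about 1 in 20 groups, or 3.3 of the 66 examined, and 12 were singled out, 10 of them through shNC replicate 4 or shYAP1_H2O2 replicate 3. Mitochondrially encoded genes took 13.9% of counts in shNC replicate 4 (4.91% to 5.04% in the others of its group) and 11.3% in shYAP1_H2O2 replicate 3 (4.54% to 4.86%). The 20 most abundant genes took 18% and 15.8% (10.1% to 10.2% and 9.34% to 9.65% in the others). In shNC replicate 4 HAVCR1 stood at 502.0 CPM (333 to 343 in the others) and LMNB1 at 160.8 CPM (212 to 216). In shYAP1_H2O2 replicate 3 IL6 stood at 47.2 CPM (36.1 to 36.7), HAVCR1 at 257 CPM (183 to 193), MKI67 at 425 CPM (256 to 264) and FN1 at 12994 CPM (9114 to 9623). CCN1 in shYAP1_H2O2 replicate 2 was low at 1561 CPM (1601 to 1609), and CCN2 in shNC replicate 2 at 121 CPM (143 to 148).

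The 2 libraries differed from their groups in many genes, with 14.6% of genes in shNC replicate 4 and 10.3% in shYAP1_H2O2 replicate 3 outlying in the same sense, against 0.498% to 2.11% in the other 10. A swap between their groups is argued against, since both, 2 of 2, correlated best with their own group once values were centred (mean r across genes of 0.450 and 0.332). Mitochondrial transcripts as the whole cause are argued against too. Without those genes the chi-square per gene fell from 153.5 and 103.8 to 58.7 and 47.1. These values were still at least 9.35 times that of the highest other library (5.04). Correction for GC content and length left 78.8% and 93.4% of the variance of their deviations, which counts against such a bias as the whole cause. A GC trend was present in shNC replicate 4, with a log2 change of -0.52 from low to high GC content. The other shNC libraries had changes of 0.002 to 0.038, and shYAP1_H2O2 replicate 3 went the other way (0.165). The deviations of the 2 libraries from their group means correlated at 0.389 across genes. Other pairs of an shNC and an shYAP1_H2O2 library gave -0.222 to 0.126. The group means include the 2 libraries, which shapes the deviations of the others too, so that range is no separate baseline. A difference in handling, RNA or sequencing run that both share may remain, but no label ties a library to either instrument and no biological explanation was tested.

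Genes of whole chromosome regions were shifted together in the shNC_H2O2 libraries, and chance order along the chromosomes is argued against by 11 windows beyond every shuffle. GC or length bias is argued against by the chromosome 3 region, whose median was -0.61 after correction, and H2O2 exposure by itself by the median of -0.013 of that region in the labelled knockdown libraries, which also received H2O2. Cells of another chromosome content in shNC_H2O2 stay open as a hypothesis, because the shares of lower genes in the 3 terciles of expression (84.5%, 90.5% and 94.0%) decide nothing in a region chosen for its lower genes. Such cells may have come from another stock of the line or may have grown out under H2O2, and DNA was not analysed here.

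Genes that differed in opposite directions in the first 2 comparisons (5349 against 355 in the same direction) would arise in part from the shNC_H2O2 libraries that both comparisons share, but with these libraries split between the comparisons at least 94.0% still went opposite ways. The regional shifts alone are argued against by 4465 opposite and 382 same-way genes after their removal. Less H2O2 acting on the labelled knockdown cells may account for part or for the whole. Of the 1119 genes called at 2-fold or more against shNC, 32.4% were not called the same way with H2O2. Among these, 311 were not called and 52 went the other way. These values cannot decide the question, because a gene not called may still have changed and shNC_H2O2 carried regional shifts of its own. Another stock of the line in shNC_H2O2 cannot be told apart from the treatment, because both would share the groups. Of genes with a mean of at least 5 CPM 50.4% were called even on chromosomes with an absolute median under 0.1. Some of these chromosomes still held shifted windows. An action of the YAP1 hairpin stays open as well, since YAP1 differed by -0.29 (-0.32 to -0.22 with each library left out in turn, and -0.18, no longer passing, with the regional shift removed) and cells with the hairpin and no H2O2 were not analysed here.

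Chance assignment of libraries to groups was tested by refitting edgeR to each of the 35 splits of the 8 libraries of a comparison. In shNC_H2O2 against shNC the real split called 9288 genes, in shYAP1_H2O2 against shNC_H2O2 8895 and in shYAP1_H2O2 against shNC 4950. In each case 1 of 35 splits, the real one, gave as many, a share of 2.86%, the smallest that 35 splits allow. Every other split mixed the groups, so a difference between them entered the spread and lowered the calls. This argues against chance assignment of these libraries only at that level. It says nothing of chance differences between cultures, because the labels do not state separate cultures. The highest of the other splits gave 0 genes in edgeR in each comparison, where 1913, 2496 and 2570 genes had an unadjusted p under 0.05 in the split with the most, against 10423, 10081 and 7047 in the real one.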

How the results depend on the processing

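The tests without the 2 libraries of high mitochondrial share, with the regional shift removed and with GC content and length corrected were chosen only after the data had been seen. Counts of changed genes stayed within 1.5 times the reported 8971, 8288 and 6265 (in the order of the 3 comparisons) with DESeq2 (9342, 8552 and 6589), limma-voom (9002, 8279 and 6279), library sizes alone (8895, 7981 and 5994), only the 2 groups compared (9288, 8895 and 4950), GC content and length corrected (9391, 8722 and 6830), the regional shift removed (8108, 7371 and 6146) and without the 2 libraries (11603, 11194 and 9146). Leaving out each library in turn gave 8067 to 10038, 7196 to 9684 and 5346 to 7298 genes, 4642 to 6025 genes with opposite directions, 15 to 19, 17 to 20 and 13 to 15 lists, and YAP1 differences of 0.20 to 0.27, -0.32 to -0.22 and -0.09 to 0.02. Of 640 called results of 270 named genes 551 kept their call and direction in all 24 settings. Same replicate numbers did not pair the libraries (correlations of deviations of -0.000364 to 0.0145, -0.0307 to 0.0145 and -0.222 to 0.103), and the fit with the number as a block called 8536, 7798 and 5731 genes, 5033 opposite genes and 15, 19 and 13 lists, with YAP1 at 0.24, -0.29 and -0.05. Fewer genes passed the stricter thresholds by construction, 2649, 2059 and 1119 at 2-fold, 4118 at an adjusted p under 0.01 in the third comparison, and 1390 opposite genes (10 in the same direction) at 2-fold in both. With the correlation between genes estimated from the data camera called 0, 0 and 3 of 45 lists (11, 7 and 10 at an unadjusted p under 0.05, smallest adjusted p 0.113, 0.125 and 0.0395), and fry, which tests a set by itself, called 32, 36 and 34. The YAP1 difference between shYAP1_H2O2 and shNC_H2O2 no longer passed with the shift of the 51 genes around it removed (-0.18, edgeR adjusted p = 0.0552). The 20 Mb window of YAP1 had a median of 0.04 in that comparison.

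Among the genes and lists named, directions turned in the following cases, and the cause was not tested except where the construction shows it. A turn was counted only where a result was called with the reported or the alternative setting and changed sign. Medians of sets that did not pass could also cross 0. That of actin cytoskeleton genes with H2O2 was 0.06, and -0.02 with the shift of neighbouring genes removed. Tubular injury genes turned under fry, up with H2O2 (adjusted p = 0.00560) and down in the labelled knockdown libraries against shNC_H2O2 (adjusted p = 0.00919). Without the 2 libraries the mitochondrially encoded list turned down in that second comparison (adjusted p = 0.000133), with MT-CO1 at -0.22, MT-ND4 at -0.24 and CDKN2A at -0.17. Removing the shift of neighbouring genes takes the regional part out of each gene by construction, and over all genes 49, 52 and 0 were then called in the opposite direction. With H2O2 against shNC it gave WWTR1 0.23, AMOTL2 0.029, CHAF1A -0.023, CHAF1B -0.15, ATR 0.20, ATP6V1A 0.15, LSS -0.16 and RPS16 -0.13, and in the second comparison WWTR1 -0.095, RFC4 -0.25, ATR -0.21, NDUFS1 0.0052, WDR12 0.061, ECT2 -0.073 and RPS16 0.10. Depth limited what could be seen below 0.0644 to 0.0974 CPM, the worth of 3 counts in a library. The 4 libraries per group limited what could be seen of small changes. In data simulated for H2O2 against shNC 48% of genes changed 1.5-fold were recovered. Only 200 of 19268 genes changed there, against 8971 called in the real comparison, so this share does not give the real sensitivity.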

Other observations

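Several groups of genes fixed beforehand had members that changed strongly with H2O2 although the group as a whole did not pass. Counts adjusted over the list alone were equal to those over all genes unless given. Among 8 NADPH and other oxidases, which produce reactive oxygen, 5 fell and 2 rose (set adjusted p = 0.0633, and 0.0411 without the 2 libraries of high mitochondrial share). DUOX1 went from 10.3 to 2.67 CPM (-1.95 ± 0.15) and the monoamine oxidase MAOA fell by 2.20 ± 0.13, and both were higher in the second comparison, the labelled knockdown libraries against shNC_H2O2 (2.23 ± 0.15 and 2.09 ± 0.13, with 3 of the list higher and 1 lower, set adjusted p = 0.113). Apoptosis regulators were higher in 12 of 24 and lower in 4 with H2O2 (13 and 4 adjusted over the list alone, 13 and 7 without the 2 libraries, set adjusted p = 0.219), with the BH3-only genes HRK (1.86 ± 0.13) and BMF (1.72 ± 0.10) among the former and the inhibitor BIRC3 (-1.85 ± 0.10) among the latter. In the second comparison 6 were higher and 10 lower (adjusted p = 0.492), and BMF was lower (-1.21 ± 0.10). Interferon-stimulated genes were higher in 11 and lower in 7 of 29 (adjusted p = 0.399), with IFI44L at 1.94 ± 0.15 and OAS3 at -0.70 ± 0.12, and in the second comparison higher in 5 and lower in 10 (adjusted p = 0.185, and 2 and 8 with the shift of neighbouring genes removed). Genes of mesenchymal transition rose in 7 of 13 and fell in 1 (adjusted p = 0.0960, and 0.0162 without the 2 libraries), among them SNAI2 (65 to 185 CPM, 1.51 ± 0.14), and were lower in 4 and higher in 1 in the second comparison (5 and 1 adjusted over the list alone, adjusted p = 0.0521), but lower in 10 and higher in 1 without the 2 libraries of high mitochondrial share (adjusted p = 0.00305). Integrins and focal adhesion genes were higher in 8 and lower in 4 of 20 with H2O2 (adjusted p = 0.419), and lower in 11 and higher in 4 in the second comparison (adjusted p = 0.0772, and 0.0114 without the 2 libraries). ITGB6, an integrin subunit that overlaps another gene, rose by 2.31 ± 0.08 with H2O2 and was lower in the second comparison (-3.39 ± 0.09). Actin cytoskeleton genes driven by SRF were split, 7 higher and 6 lower of 24 with H2O2 (adjusted p = 0.992, median 0.06 and mean 0.01 against a downward test), and 6 and 7 in the second (7 and 9 adjusted over the list alone, adjusted p = 0.921), and 11 and 9 with H2O2 and 9 and 11 in the second without the 2 libraries.

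Lipid use and tubule identity moved gene by gene. Of 21 genes of fatty acid oxidation and PPAR targets 5 rose and 5 fell with H2O2 (5 and 6 adjusted over the list alone, adjusted p = 0.776, with a downward test against a mean of 0.06). CPT1A, which carries fatty acids into mitochondria (5.73 to 25.8 CPM, 2.17 ± 0.12), and ANGPTL4 (2.59 ± 0.12) rose and the lipid droplet protein PLIN2 fell (-1.27 ± 0.08). In the second comparison 8 were higher and 4 lower (8 and 5 adjusted over the list alone, adjusted p = 0.534, and 8 and 7 without the 2 libraries), with PLIN2 (1.04 ± 0.08) and PPARG (1.06 ± 0.08) higher and CPT1A lower (-1.25 ± 0.12). Proximal tubule genes were higher in 3 and lower in 4 of 14 with H2O2 (adjusted p = 0.990, and 5 and 4 without the 2 libraries), and higher in 6 and lower in 2 in the second comparison (adjusted p = 0.275, and 8 and 4 without them), and the peptidase DPP4 was at 256, 130.4 and 254 CPM in shNC, shNC_H2O2 and shYAP1_H2O2 (-0.97 ± 0.08 and 0.96 ± 0.08). HAVCR1 (1.39 ± 0.13) and LCN2 (1.91 ± 0.30) were higher in the labelled knockdown libraries than in shNC_H2O2, while tubular injury genes were split, 11 higher and 7 lower of 24 (adjusted p = 0.610). Ligands and receptors of the EGF family and related growth factors were split 4 and 5 of 15 in both comparisons (adjusted p = 0.776 and 0.963), with VEGFC at 2.48 ± 0.13 and -2.36 ± 0.13. Histones were higher in 3 and lower in 1 of 10 with H2O2 (adjusted p = 0.0783, and 0.0343 with the shift of neighbouring genes removed), H2AC6 by 1.91 ± 0.12, and higher in 1 and lower in 2 in the second (adjusted p = 0.584). The library preparation selects polyadenylated RNA, so these levels do not stand for the bulk of histone transcripts.

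Mitochondrially encoded genes, whose share set the 2 libraries apart, were called in 0 of 15 cases by edgeR with H2O2 (set adjusted p = 0.419) and in 1 in the second comparison, MT-RNR1 (1.66 ± 0.30, set adjusted p = 0.691). More were called without these 2 libraries, where 6 were higher and 2 lower with H2O2 (adjusted p = 0.258), and 2 higher and 11 lower in the second comparison (adjusted p = 0.000133). Abundant noncoding RNA read as a sign of RNA quality fell in 2 of 6, NEAT1 among them (-0.56 ± 0.18, adjusted p = 0.0193), with a set adjusted p = 0.419, and rose in 2 in the second comparison (adjusted p = 0.672). Markers of cell types other than tubule epithelium were low or moved apart. Immune cell markers had 5 tested members, 2 of them lower with H2O2 (adjusted p = 0.352) and 2 higher in the second comparison (adjusted p = 0.294), the most abundant being CSF1R at a mean of 21.5 CPM. Endothelial markers had 3 tested members, the most abundant EGFL7 at 15.1 CPM. Fibroblast and pericyte markers were higher in 4 and lower in 4 of 9 (adjusted p = 0.992, median -0.49 and mean 0.04), with LUM at 1.13 ± 0.07 and the most abundant, MCAM, at a mean of 161 CPM and -1.14 ± 0.07, and in the second comparison higher in 3 and lower in 2 (adjusted p = 0.672). Of other nephron segments 4 markers were tested, among which SCNN1A, at a mean of 92.2 CPM, fell by 1.56 ± 0.17 and PODXL rose (2.08 ± 0.09).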
